A study of Gossypium hirsutum with 8 samples.

How the data were processed

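The samples were 8 arrays of total RNA from cotton cultivar Sicot 71, in 4 groups of 2: roots flooded for 4 h, control roots, first leaves flooded for 24 h and control leaves. Groups and replicate numbers were taken from the labels, which call the replicates biological. The authors deposited 1 table of log2 signals for 24132 probe sets, and 0 of its columns lacked a sample. RMA and limma are named in the submitters' processing notes, with no version, and the role and order of the tools are not given there. RMA in general corrects background, normalizes and summarises probes into log2 intensities, and it compresses small signals, so that folds of dim genes may be understated. They carry no detection call, and none was used here. Root and leaf arrays had different lower ends (3.99 to 4.10 and 2.49 to 2.65), so the tissues were not on a common scale and levels were compared only within a tissue except where stated.

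Signals were analysed as deposited, with no filter on low values and no pseudocount. The 103 control probe sets of the manufacturer were left out, and 52 reporter probe sets stayed in. A linear model with 1 mean per group was fitted over the 8 arrays in limma 3.58.1 (R 4.3.3), with 4 residual degrees of freedom and a prior of 3.48, and contrasts were tested with moderated statistics and Benjamini-Hochberg adjustment at 0.05. The contrasts were flooded minus control in root, flooded minus control in leaf, the difference of these, and control root minus control leaf. Overlap was tested with Fisher's exact test, and gene lists with camera at a preset correlation of 0.01 and with an estimated one, adjusted over the 8 lists of at least 3 members. The p-values measure the spread between the 2 arrays of a group, and how many plants each array stands for is not given in the sources used here. One spread shared by the 4 groups was used because each group has only 2 arrays.

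Gene names came from the platform's probe table, updated through gene identifiers to the RefSeq gene table of assembly Gossypium_hirsutum_v2.1. The probe table gave 1 gene for 697 probe sets, all matched, several for 46, and none for 23286 of those tested. A name other than a locus number was found for 324 probe sets of 246 genes, 1.35% of those tested. Upland cotton carries A and D copies of most genes, and probe sets may read both, so the copy is uncertain. The symbols ACS, GS, TPS1 and CEL have more than 1 use, and what these genes encode is uncertain. The symbol shown for 3 genes with several synonyms was chosen after the values were seen, which changed no selection.

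Before the data were examined, 17 gene lists and the rule for named genes were fixed. The patterns that match list members to symbols were written after the annotation was seen and before any fold change. Of the lists, 14 had members, fermentation had 0, and for 2, other low-oxygen responses and heat shock, no name matched. For each flooding contrast, the rule took probe sets with a gene name, an adjusted p under 0.05, a change of at least 2-fold and both flooded arrays beyond both control arrays. It named the 10 largest rises and 10 largest falls, with 1 probe set per gene (smallest p), and up to 3 members of each list with the smallest p. For the 2 other contrasts it named the 5 largest each way. List members called beyond these 3 were named after their values were seen, as were the genes called in both tissues.

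The fit was tested on simulated data with the control means and the moderated spreads of 24029 probe sets. In each of 10 draws, 200 were changed between flooded and control root. With equal spreads, 93% of changes of 2 log2 units and 19.7% of changes of 1 were called, with 6.24% false calls. With the unequal group spreads seen here, false calls were 16.2%. The Benjamini-Hochberg cutoff depends on the share of changed probe sets, and the real root contrast called many more (2566). The sizes of these rates therefore do not carry over to the real fit, and changes in leaf were not simulated. The unequal spreads are those of the real data. The root mean square SD of the 2 arrays was 0.477 in control and 0.208 in flooded root, against 0.315 and 0.193 in leaf. Adjusted p-values in root may therefore be too small. Alternatives covered the variance model, array weights, normalization, filters, thresholds, each tissue alone, the replicate number as a block and each array left out in turn. Other splits of the samples were not counted because groups hold fewer than 3 arrays.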

Results

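Transcript levels in upland cotton (Gossypium hirsutum, cultivar Sicot 71) were measured on the Affymetrix cotton array, which reads each transcript through groups of short oligonucleotides called probe sets. The 8 arrays fell into 4 groups of 2 biological replicates. Whole roots came from plants with the root system under water for 4 h and from plants watered as usual. First leaves came from plants flooded for 24 h and from their own unflooded controls. The series asks which transcripts respond to waterlogging in each tissue. The deposited values were RMA signals on the log2 scale for 24132 probe sets, of which 24029 were tested after 103 control probe sets of the manufacturer were left out. Medians were 6.14 to 6.17 on the root arrays and 5.32 to 5.41 on the leaf arrays. The number of arrays limits the precision: an exact permutation test of 2 against 2 arrays cannot go below p = 0.333 (two-sided), so all calls rest on limma, which pools the spread over probe sets and groups. The replicates of control root correlated least (r = 0.953 across probe sets), against 0.984 in control leaf, 0.991 in flooded root and 0.994 in flooded leaf. Only 324 of the tested probe sets carried a gene name other than a locus number, so the genes named here are a small part of the response.

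Flooding for 4 h raised AOX1, SusA1, MYB5 and ERF7 by the largest measured folds among the named genes of the root, each gene being read by its probe set of smallest p (a second probe set of PAP1 had a log2 change of 3.47). AOX1 (LOC107939301), the alternative oxidase that passes electrons to oxygen outside the cytochrome pathway of mitochondria, went from 6.97 ± 0.00 to 10.80 ± 0.78 (SD, n = 2 per group), a 14.2-fold rise (log2 change 3.83, SE 0.34, limma adjusted p = 0.00067). SusA1 (LOC107910106), a sucrose synthase that cleaves sucrose without spending ATP, rose 11.5-fold, from 5.60 ± 0.78 to 9.12 ± 0.11 (SD, n = 2; limma adjusted p = 0.00089). The transcription factors MYB5 and ERF7, the latter of the ethylene response factor family, rose 11.1-fold (SE 0.32 on the log2 scale) and 9.79-fold (SE 0.35). The order of these 4 was not tested. The largest falls among the named genes were in POX10, a peroxidase, which dropped from 12.65 ± 0.31 to 9.51 ± 0.61 (SD, n = 2; 8.86-fold), and EXPA3D, an expansin that loosens cell walls, which fell 7.73-fold. The EXPA3D call was lost without flooded root replicate 1 (log2 change -2.64, limma adjusted p = 0.088), and the change was -3.84 and -2.06 without control root replicate 1 and 2.

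The other large rises of named genes in root were ASP3 (log2 change 2.98), GEPH (2.53), BNLGHi8377 (2.15), ACS (2.00), the transcription factor RAV (1.90) and GOX (1.88). After POX10 and EXPA3D, the falls were led by Pel, a pectate lyase (-2.70, SE 0.17), DFR, the dihydroflavonol reductase of anthocyanin synthesis (-2.61, SE 0.28), XTH, a xyloglucan endotransglucosylase (-2.60, SE 0.59), GHMYB36 (-2.37), E6 (-2.37), PGIPL (-2.29), H6L (-2.20) and ANT1 (-2.13). In each of these genes both flooded arrays lay beyond both control arrays, because the rule that named them required it. Some of the named genes were dim in one group. The 52 reporter probe sets had a mean of 5.49 and a 95th percentile, a bound chosen after seeing the data, of 6.43 in control root, and 5.26 and 6.13 in flooded root. The medians of all probe sets were 6.16 and 6.17 on the control root arrays and 6.14 on the flooded ones. Lying under a bound is therefore common and does not set a gene apart. Under those bounds lay SusA1, MYB5 (5.77), ERF7 (6.36), ACS (5.65) and RAV (5.18) in control root, and EXPA3D (5.61), Pel (5.56) and GHMYB36 (5.94) in flooded root, so that their folds are lower limits if that level is background. The same holds for Mn-SOD (6.21) and CHS3 (5.27) in control root, named below. Probe sets of one gene did not always move together. The ACS rise was seen in 1 probe set of 4, the other three lying between -0.10 and 0.20, and for XTH, Pel and MYB5 a second probe set did not pass the test. Of the 20 genes with the largest changes, 6 lost their call without 1 of the root arrays. ACS and XTH were lost without flooded root replicate 1, where they stood at 1.21 and -1.98, and without either control root array, PGIPL without any 1 root array but control root replicate 1, EXPA3D and RAV without flooded root replicate 1, and ANT1 without flooded root replicate 2.

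Among the gene lists, the cell wall list moved down in root (median log2 change -0.97, limma camera adjusted p = 1.4e-10 at a preset correlation of 0.01, and adjusted p = 0.087 with an estimated correlation). Camera set each list against all 24029 probe sets, while list members could come only from the 324 named ones. Of those 324, 31 rose and 56 fell in root. Over all 24029, 1537 rose and 1029 fell, so falls were more common among the named ones. No test set a list against the other named genes. Of the 37 cell wall probe sets, 15 fell, 0 rose and 22 did not pass the test. Adjusted over the list alone, 19 fell. The falls covered 11 genes, among them the expansin EXPA3D, the cellulose synthase CelA1 (-1.60) and the fasciclin-like arabinogalactan proteins fla-12 (-1.94), FLA13 (-2.01) and FLA15 (-1.86). The number of falls was 1 without flooded root replicate 1, 7 without flooded root replicate 2 and 9 without either flooded leaf array, with 0 rises each time. The list of cytoskeleton and cell division had 4 falls and 0 rises among 15 probe sets, or 8 falls adjusted over the list alone. All 4 were tubulins, the building blocks of microtubules: TUA10 (-1.59), BTub3 (-1.52), TubA2 (-1.43) and BTub4 (-0.67). Its camera adjusted p was 1.5e-05, and adjusted p = 0.087 with an estimated correlation, and 8 fell after quantile normalization over the 8 arrays. Of 10 phenylpropanoid and terpenoid probe sets, 3 fell and 1 rose, or 4 and 1 adjusted over the list alone. DFR fell with CCoAMOT2 (-1.78), an enzyme of lignin monomer synthesis, and with cdn1 (-1.17), a delta-cadinene synthase of the gossypol pathway, while the chalcone synthase CHS3 rose (1.01). This list had camera adjusted p = 0.01, adjusted p = 0.34 with an estimated correlation, and adjusted p = 0.091 at the preset correlation without control root replicate 2. Its falls numbered 1 without flooded root replicate 2 and 6 without control root replicate 1, and the rise of CHS3 was lost in limma without any 1 of the flooded arrays of either tissue (0 rises, 1 at an unadjusted p under 0.05) and with the replicate number as a block.

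The remaining lists did not pass as sets in root, except that ribosome and translation passed without control root replicate 2 (median -0.60, camera adjusted p = 0.017, and adjusted p = 0.38 with an estimated correlation). Of 4 sucrose breakdown probe sets, 2 rose, both of SusA1, and susC stood at -0.60 (adjusted p = 0.21); the count adjusted over the list alone was also 2. Of 14 ethylene probe sets, 2 rose (ERF7 and ACS) and 2 fell, ACS1 (-1.06) and ACS3 (-1.70), with the same counts adjusted over the list alone. Of 23 oxidative stress probe sets, 2 rose, Mn-SOD (1.48), a superoxide dismutase, and pod7 (0.78), and 3 fell, all peroxidases; adjusted over the list alone these counts were 4 and 3. Of 16 probe sets for abscisic acid, jasmonate, auxin and gibberellin, 4 rose and 3 fell, or 6 and 4 adjusted over the list alone. The rises were 2 probe sets of Aux4 (1.68 and 1.80), the lipoxygenase Lox1 (1.80) and the late embryogenesis abundant gene Lea5-D (1.72), and the falls included GAI2 (-1.24) and the gibberellin receptor GID1-4 (-0.96). In the list of ribosome and translation, EF1A7 fell (-0.78) and 5 probe sets did not pass; adjusted over the list alone 1 fell. The camera adjusted p-values of these 5 lists lay between 0.18 and 0.91. Leaving out single arrays, and with them the spread of their pair, moved the counts in limma. For oxidative stress, 6 rose without control root replicate 1 and 0 without flooded root replicate 2 (5 at an unadjusted p under 0.05), 1 rose without flooded root replicate 1 or either flooded leaf array, and 1 fell without flooded root replicate 1. For the hormone list, 0 fell without any 1 of the flooded arrays (3 or 4 at an unadjusted p under 0.05), 6 fell without control root replicate 1, and 2 rose without either flooded root array. For ethylene, 1 rose without any 1 array but flooded root replicate 2, 0 fell without that array (2 at an unadjusted p under 0.05), and 1 fell without flooded root replicate 1 or either flooded leaf array. For sucrose breakdown 1 rose without flooded root replicate 1, and for ribosome and translation 0 fell without any 1 of the flooded arrays (1 at an unadjusted p under 0.05). Lists with 1 member were not tested as sets: the photosynthesis gene RCA1 stood at -0.34 (adjusted p = 0.47), the aquaporin NIP6.1 at -1.04 (0.17), GS at 0.84 (0.12) and TPS1 at -0.38 (0.44).

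Across all probe sets, limma called 2566 in root at an adjusted p under 0.05, 1537 higher and 1029 lower after flooding, and 2129 of these changed at least 2-fold. Rises and falls were closer in number after quantile normalization over the 8 arrays (1636 and 1526) and within each tissue (1525 and 1421). The count moved when 1 array was left out, and without control root replicate 2 falls outnumbered rises. Leaving out an array also removes the spread of its pair from the variance that the 4 groups share. That spread (root mean square SD) was 0.477 in control root and 0.208 in flooded root. The moves in count therefore mix the values of an array with the shared variance. With the root arrays fitted alone 1021 probe sets were called, and with array weights 1399.

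**Figure D1:**
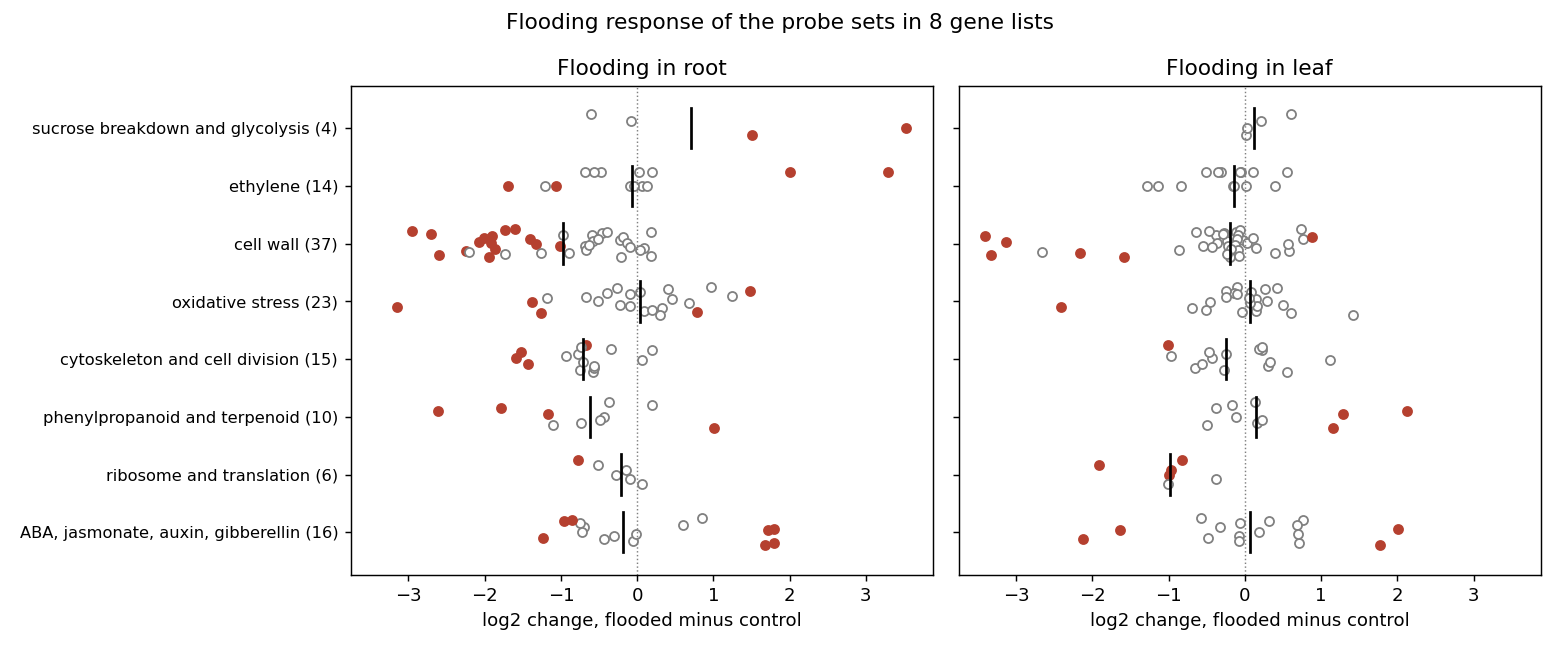
Log2 change after flooding (horizontal axis, flooded minus control, limma) of every probe set in the 8 gene lists with at least 3 members, in root after 4 h and in leaf after 24 h. Each point is a probe set, filled points passed the adjusted p threshold of 0.05, black bars mark list medians, and the numbers in brackets count probe sets. The cell wall list had a median of -0.97 in root and -0.19 in leaf.

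In the first leaf, 24 h of flooding raised NIP6.1 (LOC107906429), an aquaporin of the NIP type, 4.52-fold, from 5.65 ± 0.27 to 7.83 ± 0.21 (SD, n = 2; log2 change 2.18, SE 0.40, limma adjusted p = 0.026). DFR (LOC107957957) rose 4.37-fold, from 7.55 ± 0.33 to 9.68 ± 0.12 (SD, n = 2; limma adjusted p = 0.012). The largest falls among the named genes were in FLA (LOC107954983), a fasciclin-like arabinogalactan protein of the cell wall, which dropped 10.7-fold from 9.07 ± 1.12 to 5.65 ± 0.32 (SD, n = 2; limma adjusted p = 0.013), and in XTH, which dropped 10.1-fold (limma adjusted p = 0.025). Without control leaf replicate 1 and 2 the log2 change was -4.21 and -2.62 for FLA and -2.47 and -4.19 for XTH.

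The other leading rises of named genes in leaf were Ssh2 (1.78), Aux4 (1.77), Pat1 (1.55), the transcription factors NAC5 (1.48) and MYB1 (1.19), cdn1 (1.29), MFS (1.18) and CHS3 (1.16). The falls after FLA and XTH were GRPL1 (-2.53), POX10 (-2.41), FLA4 (-2.17), LEGB (-2.12), the late embryogenesis abundant gene Lea14-A (-2.12), the translation elongation factor EF1A7 (-1.92), RPS4 (-1.82) and the annexin AnnGh1 (-1.77). SEs of these log2 changes ran from 0.17 for MFS to 0.59 for XTH. In control leaf cdn1 (4.00), NAC5 (4.80) and Pat1 (5.04) lay under the 95th percentile of the reporter probe sets (5.60), so their rises are lower limits if that level is background. That bound also lay above the medians of the control leaf arrays (5.41 and 5.37). Every one of the 20 leading genes of the leaf lost its call without either flooded leaf array, and all but FLA also without at least 1 control leaf array.

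The list of ribosome and translation was lower in leaf (median -0.98, camera adjusted p = 0.00016 at the preset correlation, and adjusted p = 0.49 with an estimated correlation). Of all 324 named probe sets, 16 rose and 21 fell in leaf. Of the 6 probe sets of the list, 4 fell and 0 rose, and 5 fell adjusted over the list alone. The 4 probe sets belonged to 3 elongation factor genes, EF1A7 (-1.92 and -0.83), EF1A2 (-0.99) and EF1A1 (-0.97), and the ribosomal protein members RL37a (-1.01, limma adjusted p = 0.14) and RL44 (-0.38, limma adjusted p = 0.77) did not pass. The genes RPS4 and RPS16 (-1.73) were not in the list as matched, and with them counted in 6 of 8 fell (camera adjusted p = 9.7e-07, and adjusted p = 0.49 with an estimated correlation). None of its probe sets passed singly in limma without any 1 of the leaf or flooded root arrays (4 or 5 fell at an unadjusted p under 0.05), and 5 fell without either control root array. Of 37 cell wall probe sets, 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.1, and adjusted p = 0.49 with an estimated correlation). The falls were FLA (2 probe sets), XTH, FLA4 and fla-12 (-1.58), and the rise was a probe set of Pel (0.88) other than the one that fell in root. As a set it passed without control leaf replicate 1 (camera adjusted p = 0.011, and adjusted p = 0.67 with an estimated correlation) and without flooded leaf replicate 2 (adjusted p = 0.046, and adjusted p = 0.73 with an estimated correlation). In limma 0 of its probe sets passed singly without flooded leaf replicate 1 or 2 (6 and 8 fell and 2 and 1 rose at an unadjusted p under 0.05), 3 fell without control leaf replicate 1, and 2 fell without control leaf replicate 2 or either flooded root array. Of 10 phenylpropanoid and terpenoid probe sets, 3 rose (DFR, CHS3 and cdn1) and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.13). In limma 1 rose without control leaf replicate 1 or either flooded root array, and 0 without any 1 of the other leaf arrays (3 at an unadjusted p under 0.05).

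Of the 16 hormone probe sets of the leaf, 2 rose, both of Aux4, and 2 fell, Lea14-A and Lea5-D (-1.64); adjusted over the list alone 4 rose and 2 fell. POX10 was the only one of 23 oxidative stress probe sets past the threshold, and BTub4 (-1.01) the only one of 15 for cytoskeleton and cell division. Adjusted over the list alone, 1 rose and 1 fell among the former and 3 fell among the latter. In limma 0 hormone probe sets passed without either flooded leaf array or control leaf replicate 2 (4 or 5 rose and 2 or 3 fell at an unadjusted p under 0.05), 4 rose without either control root array, 1 rose without control leaf replicate 1, and 1 fell without either flooded root array. The calls of POX10 and BTub4 were lost without any 1 of the leaf arrays, and that of BTub4 also without either flooded root array. Without either control root array 1 oxidative stress probe set rose and 2 cytoskeleton probe sets fell. No probe set of the ethylene or the sucrose breakdown list passed, either way of adjusting: ACS3 stood at -1.28 (adjusted p = 0.086), ERF8 at -0.84 (0.075) and SusA1 at 0.03 (0.98), while 1 ethylene probe set fell without any 1 of the root arrays. The camera adjusted p of these 5 lists lay between 0.29 and 0.64. AOX1 stood at -0.09 (adjusted p = 0.95), RCA1 at 0.09 (0.91), GS at 0.65 (0.26) and TPS1 at 0.35 (0.53). SusA1 and AOX1 read 3.59 and 4.29 in control leaf, where the reporter probe sets had a mean of 4.11, so a fall could not have been seen if that level is background. ERF8 (4.58 in control and 3.74 in flooded leaf) and ACS3 (5.44 in flooded leaf) lay under the 95th percentiles of the reporter probe sets (5.60 and 5.45). Their changes are likewise not exact if that level is background. The poly-A control transcripts added during labelling were 4.55-fold brighter on the flooded than on the control leaf arrays, beside all of these changes.

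In leaf limma called 1262 probe sets, 530 higher and 732 lower, but rises outnumbered falls after median centring (636 and 612), with array weights (1533 and 1501) and without either control root array (1654 and 1591). The count was 0 without flooded leaf replicate 1 (2642 at an unadjusted p under 0.05), 1 without flooded leaf replicate 2, 376 and 274 without control leaf replicate 1 and 2, and 2106 with the leaf arrays fitted alone. Leaving out either flooded root array, which holds no leaf values, moved the count too, through the shared variance and its degrees of freedom. The change in DFR was 2.04 and 2.21 without flooded leaf replicate 1 and 2.

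Among the named genes, the measured difference in flooding effect between root and leaf was largest for DFR, which fell in root and rose in leaf (difference of log2 changes, root minus leaf, -4.73, SE 0.40, limma adjusted p = 0.0014). The order of the differences given here was not tested. H6L (-3.34), MFS (-3.11) and cdn1 (-2.46) also fell in root and rose in leaf, while Lea5-D rose in root and fell in leaf (3.36, SE 0.37, limma adjusted p = 0.0035). MYB5 (4.15), AOX1 (3.92), SusA1 (3.49) and ERF7 (3.36) rose in root and did not pass the test in leaf, and the difference passed for each. On every leaf array these genes read under the 95th percentile of the reporter probe sets (5.45 flooded and 5.60 control). If that level is background, their leaf changes, and so the size of these differences, are not exact. NIP6.1 (-3.22) rose in leaf only at the threshold used, and EXPA3D (-2.82), in its second probe set, fell in root. The difference call was lost for EXPA3D without either flooded root array or any 1 of the leaf arrays, for NIP6.1 without any 1 of these but control leaf replicate 2, and for ERF7 without flooded leaf replicate 2 (limma adjusted p = 0.055). Without control root replicate 1 and 2 the difference was -2.57 and -3.87 for NIP6.1 and -3.45 and -2.19 for EXPA3D. Tissue and hours under water change together here, so the differences cannot be assigned to either.

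The difference passed for 1985 probe sets, with root minus leaf positive in 1152 and negative in 833, or 1655 and 2121 without control root replicate 2. A positive difference includes genes that fell more in leaf, such as Lea14-A (1.68). For the cell wall list its median was -0.34 (camera adjusted p = 0.0012, and adjusted p = 0.29 with an estimated correlation). For cytoskeleton and cell division it was -0.86 (adjusted p = 0.0057, and adjusted p = 0.29 with an estimated correlation), and for phenylpropanoids and terpenoids -0.66 (adjusted p = 0.0027, and adjusted p = 0.29 with an estimated correlation). The count was 561 and 852 without flooded root replicate 1 and 2, 5294 and 3776 without control root replicate 1 and 2, 473 and 514 without flooded leaf replicate 1 and 2, and 1263 and 1196 without control leaf replicate 1 and 2.

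**Figure D2:**
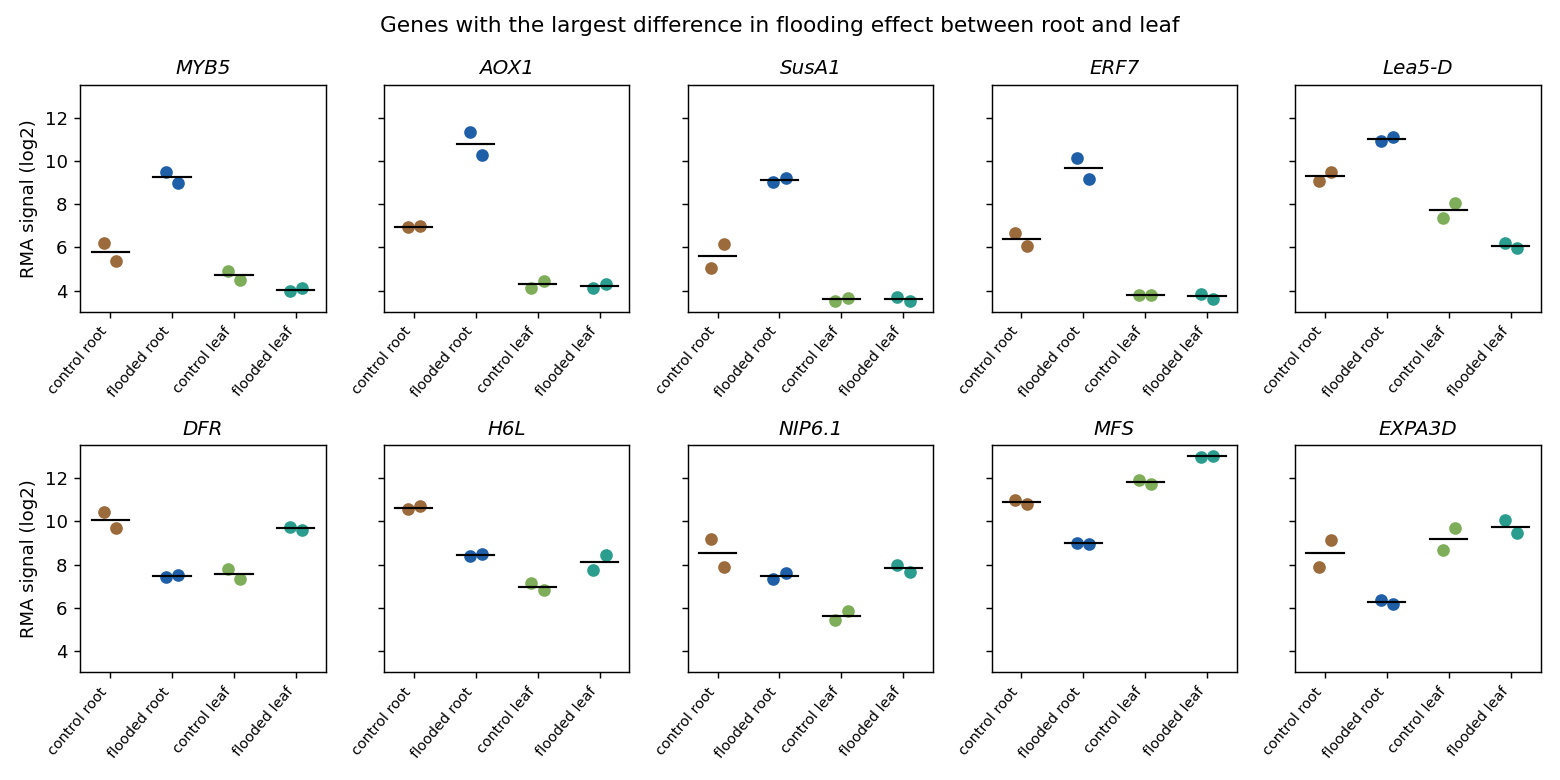
RMA signal (log2, vertical axis) of the 10 named genes with the largest difference in flooding effect between root and leaf, 5 each way. Points are single arrays, 2 per group, and black bars are group means. DFR is lower in flooded than control root and higher in flooded than control leaf, with a difference of -4.73. Root and leaf levels are not on a common scale.

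Calls in both tissues included POX10, XTH, FLA, fla-12, BTub4, EF1A7 and ManA2, which fell in both, and Aux4 and CHS3, which rose in both. In all, 158 probe sets were called in the same direction, 67 higher and 91 lower. Independent lists would share 33.9 and 31.3 (Fisher's exact test, two-sided, p = 1.2e-07 and 4.4e-20 over probe sets, which are not independent). Both contrasts use the same variance for a probe set, which could raise shared calls in either direction. It is argued against as the whole cause. With each tissue fitted alone, which shares no variance estimate, 51 were higher in both, 55 lower in both and 62 opposite. Those fits called 599 higher and 422 lower in root, and 1026 and 1080 in leaf. A probe set of low spread in both tissues could still be called in both, so the excess by itself is no evidence of a shared response. In the fit over all arrays, a further 95 were called in opposite directions. Of these, 58 were lower in root and higher in leaf, against 22.7 for independent lists (Fisher's exact test, p = 6.4e-11), DFR, cdn1, H6L, MFS and GLU among them, and 37 were higher in root and lower in leaf, against 46.8 (Fisher's exact test, p = 0.14), with Lea5-D the one named gene. The log2 changes of root and leaf correlated at r = 0.055 (Pearson) across all probe sets tested. Without either flooded leaf array both counts were 0. Without control root replicate 1 and 2, 725 and 431 were called in the same direction (526 and 175 of them higher, 199 and 256 lower) and 449 and 378 in opposite directions.

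Without flooding, RCA1 (LOC107942112) had the largest difference between control root and control leaf among the named genes. This gene, which encodes the activase of the carbon-fixing enzyme rubisco and is the 1 measured member of the photosynthesis list, read 14.55 ± 0.07 in leaf and 5.57 ± 0.45 in root (SD, n = 2; log2 difference root minus leaf -8.99, limma adjusted p = 2e-07). CBP3 (-8.56), CBP2 (-8.39), the germin-like gene Glp1 (-7.28) and f15 (-5.92) were also lower in root. The cyclopropane fatty acid synthase genes CPA-FAS-1 (7.56) and CPA-FAS-2 (7.48), cdn1 (7.53), the peroxidase pod6 (6.07) and the glutathione S-transferase GST (5.72) were higher in root. All 10 of these passed under every alternative in which they were tested, and Glp1 stood at -6.34 and -8.22 without control leaf replicate 1 and 2. In the tissue where they were lower, all of them but GST read under the 95th percentile of the reporter probe sets (6.43 in control root and 5.60 in control leaf). For the genes lower in root, the differences are lower limits if that level is background. For those higher in root they are not, because root arrays read higher throughout (reporter probe sets, median log2 difference 1.42). Their lowest values across the alternatives were 6.74 for CPA-FAS-1, 6.71 for CPA-FAS-2, 6.76 for cdn1 and 5.24 for pod6.

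The overall count of this comparison is not on a common scale. limma called 18450 probe sets, 86.6% of them higher in root, with a median log2 difference of 1.08 over all probe sets, and 48 of the 52 probe sets named as reporters on the array were also called higher in root. After quantile normalization over the 8 arrays 9460 passed, 53.9% higher in root, with a median of 0.08.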

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

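The test of the difference and the fits of each tissue alone were planned, and the comparison of effect sizes was set out before its result was seen, while quantile normalization within tissue, the use of the fits of each tissue alone to weigh unequal spread, and the tests on the control root arrays and the control transcripts were chosen after the results they bear on were seen. A test of the difference itself marked 1985 probe sets whose response to flooding differed between root at 4 h and leaf at 24 h. Among named genes the difference of log2 changes, root minus leaf, was 4.15 for MYB5, 3.92 for AOX1, 3.49 for SusA1, 3.36 for ERF7 and 3.36 for Lea5-D. It was -4.73 for DFR, -3.34 for H6L, -3.22 for NIP6.1, -3.11 for MFS and -2.82 for EXPA3D. MYB5, AOX1, SusA1 and ERF7 lay under the reporter bounds on every leaf array, and all but AOX1 also in control root. The size of their differences is therefore not exact if that level is background. Tissue and time flooded are confounded, and no test here separates them.

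More probe sets were called in root than in leaf (2566 against 1262, a ratio of 2.03). Uneven scaling of the control root arrays is argued against as the whole cause, because the ratio was still 1.83 after quantile normalization within each tissue. Unequal spread under one shared variance may account for the order of the counts: with each tissue fitted on its own arrays the ratio was 0.485, fewer calls in root than in leaf. Larger effects in root also remain open. The SD of the flooding effects, estimated from pairs of arrays that share none, was 1.34 times that of leaf in the lower of 2 pairings. In the other it was 1.41 times. The 95% interval of the lower one was 1.29 to 1.38 from a bootstrap over probe sets, which leaves out the spread between arrays and plants. The counts alone therefore do not rank the tissues, and a biological difference by tissue or time stays untested.

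Control root replicate 2 stood apart from control root replicate 1, with an interquartile range of 2.83 against 3.51 and 13.2% of probe sets over 2-fold apart. Level-dependent scaling is argued against as the main cause, because a smooth curve over the level explained 20.3% of the variance of their difference, and after quantile normalization its SD was 0.636, against 0.672 before and 0.294 in flooded root. A difference in 3' bias of the labelled RNA may contribute. Control root replicate 2 had the lowest 3' minus 5' difference of the 4 root arrays for all 3 plant control transcripts, though these share one array and so are not independent. The narrower range of this array would also lower such differences, so the test cannot tell 3' bias from that range. A difference between the plants stays open and was not tested.

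The poly-A control transcripts, which belong to no comparison of the report, were brighter in flooded than in control leaf by 2.18 on the log2 scale (9.99 ± 0.99 against 7.80 ± 0.43, SD, n = 2), with both flooded arrays above both controls. In root the difference was 0.42. Array-wide brightness is argued against, because the hybridisation controls differed by 0.12 between flooded and control leaf. Less plant mRNA per amount of total RNA in flooded leaf could give the 2.18, but so could a larger amount of control RNA added, and these cannot be told apart because the amount added is not given in the sources used here.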

How the results depend on the processing

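Alternatives in which arrays of the other tissue were left out, quantile normalization within tissue, the crossed pairing, lists refitted without single arrays or with another normalization, their estimated correlations, and the ribosome list with RPS genes (which left 4 list calls) were chosen after seeing the data. No named result changed sign where it was called, and no probe set called in a flooding contrast was called in the opposite direction there under an alternative. Of the named results not called in leaf, AOX1 (-0.09) ran from -0.26 to 0.09, Sus1 (0.21) from -0.07 to 0.50 and SusA1 (0.03) from -0.06 to 0.12. The causes of the shifts below were not tested, except for what follows from the settings themselves. A stricter threshold lowers counts by construction. Without shared probe sets 12727 of 24029 were tested, and without the lowest 40% of values 14417, so those counts come from fewer probe sets. Leaving out an array removes the spread of its pair from the shared variance, so counts of the other tissue moved too. Where an array was left out, the lone array of its group is assumed to vary like the other groups. Root calls (2566) went to 1399 with array weights, 1208 without shared probe sets (_s, _x and _a), 1198 at an adjusted p under 0.01, 1021 with root alone and 1422 with root alone after quantile normalization within tissue, and ran from 997 (without flooded root replicate 1) to 6781 (without control root replicate 1), with 1271 without flooded root replicate 2. Leaf calls (1262) went to 3034, 443, 96, 2106 and 2035 under the same changes, and from 0 (without flooded leaf replicate 1; limma, 2642 at an unadjusted p under 0.05) to 3245 (without either control root array), with 1 without flooded leaf replicate 2, 376 and 274 without control leaf replicate 1 and 2, and 413 without either flooded root array. Calls of the difference (1985) went to 924 without shared probe sets and 535 at the stricter threshold, and from 473 (without flooded leaf replicate 1) to 5294 (without control root replicate 1). Control root against leaf (18450) went to 9460 after quantile normalization over 8 arrays, with 228 calls of opposite sign, 12228 with median centring, 9164 without the lowest 40% of values and 9790 without shared probe sets. Shared calls in the same direction (158) went to 8 at the stricter threshold, and from 0 (without either flooded leaf array) to 725 (without control root replicate 1). With 1 probe set per named gene 9 of 246 were shared, against 11 of the 324 named probe sets. Of the 4 list calls, 1 was left without shared probe sets, where the other 3 lists had too few members for the test, and 0 with an estimated correlation. Without control root replicate 2 the ribosome list passed in root and the phenylpropanoid list did not, and without control leaf replicate 1 or flooded leaf replicate 2 the cell wall list also passed in leaf. Of the 36 named results called in root, 14 passed in every alternative, against 0 of 25 in leaf, 7 of 10 for the difference and 10 of 10 for control root against leaf. The shares of root and leaf do not rank the tissues, because they depend on the setting. At an adjusted p under 0.01, 11 named results lost their call in root and 25 in leaf. With each tissue fitted alone, 13 lost it in root and 0 in leaf. A pseudocount was not run because the values are logs. Dim probe sets cannot be told from background here, since no detection calls were used.

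Replicate numbers are shared in the labels, but same-numbered arrays did not deviate together (correlation 0.04 in root and -0.19 in leaf). The negative value means that leaf arrays of different number deviated together slightly. Whether those share a source was not tested. With the replicate number as a block, calls were 2275 in root, 811 in leaf, 1509 for the difference, 18263 for control root against leaf and 95 shared, and the 4 list calls were 4; with an estimated correlation the block left 1, the cell wall list in root (adjusted p = 0.033). Within 1 tissue the block gave 756 in root and 924 in leaf, and the crossed pairing gave 3159 in leaf.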

Other observations

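The lists in this part were drawn up after the data were seen, and their camera p-values were adjusted over the lists of this part only. Among 52 probe sets for transcription regulators, 6 rose and 2 fell in root. The rises were MYB5, ERF7, RAV (2 probe sets), NAC2 and COL5-D (0.96), and the falls were GHMYB36 and the DELLA gene GAI2, a repressor of gibberellin responses. In leaf 2 rose, NAC5 and MYB1, and 0 fell. The list did not shift as a set in either tissue (limma camera adjusted p = 0.084 in root and 0.42 in leaf). Of 23 probe sets for protein kinases and calcium signalling, MAPKKK rose in root (1.39) while CNGC2 (-1.57) and CRK1 (-1.51) fell, and AnnGh1 fell in leaf (camera adjusted p = 0.91 and 0.76). Of 24 for fatty acid and wax synthesis, 3FAD fell in root (-1.62) and 0 passed in leaf (camera adjusted p = 0.64 and 0.42).

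Fasciclin-like arabinogalactan proteins made up 19 of the probe sets, of which 8 fell in root and 4 in leaf, with 0 rises in either. The falls belonged to 5 genes in root and 3 in leaf, and FLA and fla-12 fell in both. The camera adjusted p was 1.4e-06 in root and 0.034 in leaf, and with an estimated correlation the adjusted p was 0.23 and 0.59. All were members of the cell wall list. Of 4 small GTPase probe sets, Rac2 fell in root (-1.33) and 0 passed in leaf; the camera adjusted p was 0.084 in root and 0.033 in leaf, where all 4 values were positive, and 0.59 in leaf with an estimated correlation.

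The largest measured changes came from probe sets with no gene name here. One rose 221-fold in flooded root (log2 change 7.79, SE 0.59) and another 159-fold, from 5.55 ± 0.47 to 12.86 ± 0.09 (SD, n = 2; limma adjusted p = 1.8e-05). The 2 control arrays of the former read 7.04 and 4.92, and its log2 change was 8.85 and 6.73 without the first and the second. The mean control levels, 5.98 and 5.55, lay under the 95th percentile of the reporter probe sets there (6.43), though 1 array of the former did not. The 159-fold rise is therefore a lower limit if that level is background, and the 221-fold rise is not exact. The unnamed probe set with the largest fall in root fell by 4.58 on the log2 scale. In leaf the corresponding rise was 10.1-fold, and the corresponding probe set fell by 4.68, or by 3.74 and 5.61 without flooded leaf replicate 2 and 1; both calls were lost without either flooded leaf array. The second probe set of PAP1, which the rule for named genes passed over for another of smaller p, had a log2 change of 3.47 in root.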
